A study of Camellia sinensis with 3 samples.

How the data were processed

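Nuclei were isolated from tender root tips of the tea plant (Camellia sinensis, cultivar Shuchazao), an evergreen shrub whose young roots are a site of theanine synthesis. Per the labels' protocols, the nuclei were partitioned in droplets with the 10x Genomics Chromium 3′ chemistry, in which each captured RNA molecule receives a cell barcode and a unique molecular identifier (UMI), and the libraries were sequenced on an Illumina NovaSeq. The series holds 1 group of 3 libraries, named here replicates 1 to 3. The labels do not say whether the libraries came from separate plants or from 1 preparation of nuclei, so every p-value below measures only the spread between these libraries, which may be technical.

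The authors deposited raw UMI counts per gene and barcode, 1 matrix per library, made with Cell Ranger 7.0.0 per the file headers. Per the series' design text, Cell Ranger was used for filtering, alignment, quantification and the calling of recovered nuclei. The genome build, the annotation and the read settings (such as whether intronic reads were counted) are not given in the sources used here. The 3 matrices list the same 50525 genes and hold 49703 barcodes in all. Every barcode carries at least 500 UMIs. The gene list holds CSS identifiers and no gene symbols. None of these identifiers (0) occurs in the RefSeq gene table used for names, which holds 80110 genes, so genes are given by identifier and at most a handful are printed. The gene lists and cell type markers fixed for this tissue before the data were examined were matched on names, so they could not be used: no list was tested, and clusters carry numbers and no cell type.

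Nuclei with at least 500 UMIs and at least 300 detected genes were kept. Doublets were scored per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.1, with its automatic threshold. It marked 0, 0 and 4 barcodes in replicates 1 to 3, under 0.03% of any library, so it did not work as a doublet filter here. Any other doublets remain in the data, and their share was not measured. The 4 marked barcodes were removed, and removal of the 10% of nuclei with the highest score was added as an alternative. After these steps 49655 nuclei remained.

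To keep genes from being tested on the counts that had defined the clusters, the UMIs of each nucleus were split at random into 2 sets by binomial thinning with probability 0.5. Clusters were made from 1 set: counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes were picked with library as batch, and 30 principal components, 15 nearest neighbours weighted by shared neighbours and the Leiden method at resolution 0.5 were used (leidenalg 0.10.2). Of 10 restarts of the Leiden method the one with the highest quality was kept. No library correction was applied before the components. Clusters were numbered by size. Agreement between clusterings was measured with the adjusted Rand index over nuclei and with the Jaccard index between a cluster and its best partner.

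The other set of counts was summed per library and cluster, which gave 21 sums of 652777 to 6063967 UMIs, and tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3. The model held cluster and library as terms, since every library held every cluster. A gene differed among clusters when the F test over all clusters gave a Benjamini-Hochberg adjusted p under 0.05. A gene was called higher or lower in a cluster when the contrast of that cluster against the equally weighted mean of the other clusters gave an adjusted p under 0.05 and a log2 fold change of at least 1 in size. That mean was taken on the log scale. A log2 fold change can therefore differ from the ratio of the mean CPM values printed beside it. In total 21375 genes were tested. Standard errors of log2 fold changes were taken from the F statistic. CPM values (UMIs scaled by the total of each sum) are of these sums, as mean ± SD over the 3 libraries. Lower limits on folds use a floor of 3 counts over the 3 libraries of a cluster, and floors cover counting error only.

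The fit was tested on simulated data: counts were drawn for the real genes from their mean shares, library sizes and dispersions, with 200 genes raised in 1 cluster. In simulated cluster 5 the fit recovered 93% of the genes raised 2.5-fold and 100% of those raised 4-fold. In simulated cluster 7, which has far fewer UMIs, it recovered 83.5% and 94.9%. False calls in the raised cluster numbered 2 and 1. All simulated clusters shared 1 mean profile apart from the raised genes. The simulation therefore says nothing about errors of scaling between clusters that differ widely.

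By the rule fixed before the data were examined, the text names, over all clusters, the 2 genes with the largest and the 2 with the lowest log2 fold change that were called and went the same way in each of the 3 libraries. The gene with the most UMIs was added after its values were seen. Alternatives fixed beforehand changed the scaling (RLE), the test (DESeq2 1.42.0), the gene filter, the block, the libraries, the Leiden resolution (0.25 and 1.0), library centring, the thinning, the doublet step, the depth minimum (500 genes and 1000 UMIs) and the reference of each contrast (the sum of all other nuclei). Alternatives chosen after seeing the data were library-size scaling only, the second best restart, 10 principal components, removal of high doublet scores, and leaving out each replicate for the shares and library values. Genes per nucleus were compared after each nucleus was thinned to 500 UMIs, which left out none.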

Results

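Single-nucleus RNA profiles of tea root tips were collected in 3 libraries of 1 group, to describe the cell populations of the root. Replicate 1 held 15809 barcodes and 33916126 UMIs, replicate 2 held 18072 barcodes and 50823069 UMIs, and replicate 3 held 15822 barcodes and 34445107 UMIs. The filters left 15786, 18067 and 15802 nuclei. The median nucleus carried 1637 UMIs and 1055 genes in replicate 1, 2101 UMIs and 1270 genes in replicate 2, and 1653 UMIs and 1062 genes in replicate 3. Over the 3 libraries 43156 of the 50525 listed genes had at least 1 UMI. The series has no second condition, so the comparisons implied by its design are those between libraries and those between the nuclear populations within the root. The files do not pair their gene identifiers with names, and no table used here does, so the populations are described by number.

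The 3 libraries gave nearly the same expression profile. Summed over nuclei, log2(CPM + 1) values correlated between libraries at Pearson's r = 0.9984 for replicates 1 and 2, 0.9983 for replicates 1 and 3, and 0.9983 for replicates 2 and 3, across 43154 genes, which are not independent replicates. Among the 12215 genes with a mean of at least 10 CPM, the median absolute log2 ratio was between 0.05 and 0.06 for each pair, and at most 1 gene per pair differed 2-fold or more. Random sets of 7500 nuclei were also compared, over genes with at least 20 UMIs in both sets together. The chi-square per degree of freedom was 1.49 to 1.68 within a library and 1.83 to 2.48 between libraries, so small differences between libraries remained. One transcript, CSS0027849, took more UMIs than any other gene in every library, with 2.99%, 3.19% and 3.02% of the total.

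In the chosen partition the nuclei fell into 7 clusters, each of which was present in all 3 libraries at a similar share. Cluster 1 held 21.6% ± 0.648 of nuclei (SD, n = 3), cluster 2 held 19.4% ± 0.43, cluster 3 held 17.8% ± 0.552, cluster 4 held 16.1% ± 0.501, cluster 5 held 10.1% ± 0.182, cluster 6 held 7.77% ± 0.328 and cluster 7 held 7.19% ± 0.773. Clusters 3, 6 and 7 held their lowest shares in replicate 2, the deepest library, with 6.39% in cluster 7 against 7.93% and 7.25%. Cluster boundaries were far less reproducible than shares between libraries. The 9 other restarts of the clustering on the same graph matched the chosen one with adjusted Rand indices of 0.412 to 0.696. Cluster 5 and cluster 2 were recovered best, with median Jaccard indices of 0.717 and 0.712 over restarts, and cluster 4 and cluster 6 worst, with 0.421 and 0.436. The shares therefore describe this partition, and most moved by more than their SD under another clustering.

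**Figure D1:**
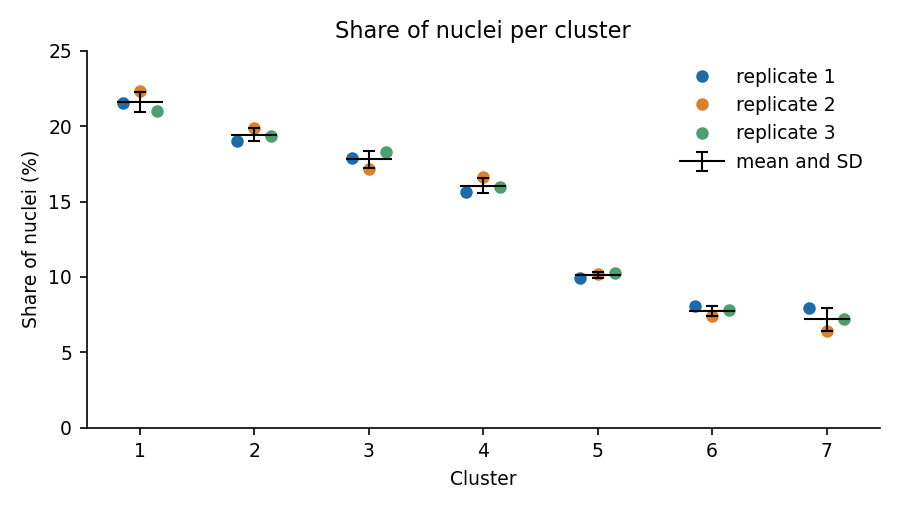
Share of nuclei (%, y axis) in clusters 1 to 7 (x axis) for replicates 1 to 3 (coloured points), with the mean (bar) and SD (whiskers) over the 3 libraries. The libraries lie close together in most clusters, from 21.6% ± 0.648 in cluster 1 to 7.19% ± 0.773 in cluster 7. The SD is largest in cluster 7 (6.39% to 7.93%).

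Clusters differed in UMIs per nucleus and in how evenly UMIs were spread over genes. Nuclei of clusters 2, 3 and 5 were the deepest, with median UMIs of 2324 ± 337, 2298 ± 439 and 2198 ± 339 (mean ± SD over 3 libraries). Nuclei of clusters 6 and 7 were the shallowest, at 904 ± 33.8 and 854 ± 14.6. At an equal depth of 500 UMIs, the median nucleus of cluster 5 carried 344 ± 1 genes, against 394 ± 0 in cluster 1 and between 409 and 415 in each of clusters 2, 3, 4, 6 and 7. The 50 most abundant genes took 23.3% ± 0.269 of the UMIs of cluster 5, 17.6% ± 0.126 of cluster 1 and 12.2% ± 0.0246 of cluster 3. In each of the 3 libraries cluster 5 had the fewest genes at this depth and the highest share in its top 50 genes. No test was run on these values.

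**Figure D2:**
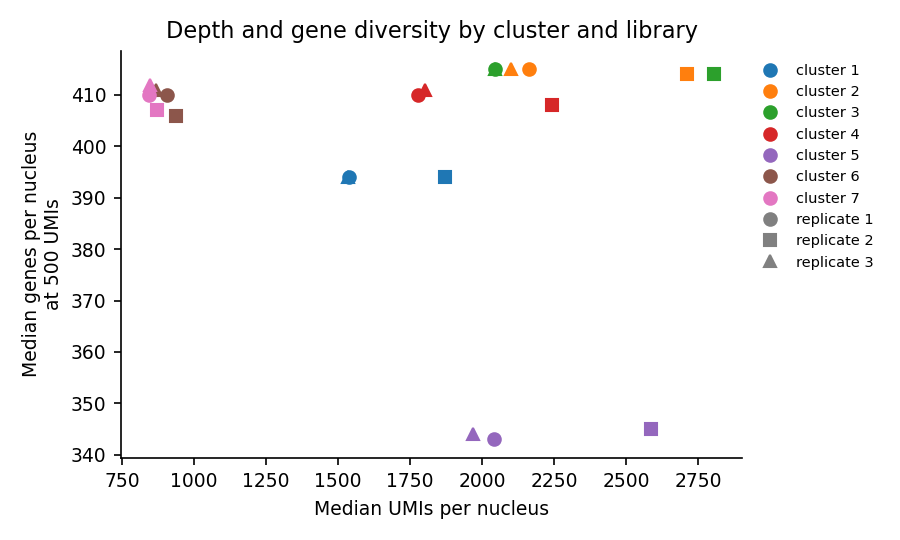
Median UMIs per nucleus (x axis) against the median number of genes per nucleus after thinning to 500 UMIs (y axis), 1 point per cluster (colour) and library (marker shape). Cluster 5 lies apart at 344 ± 1 genes although its nuclei are among the deepest, and clusters 6 and 7 lie at the left with under 1000 UMIs.

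Most of the genes that passed the count filter varied among the clusters. In edgeR's quasi-likelihood F test on the UMIs not used for clustering, 17720 of 21375 genes (82.9%) differed among clusters at an adjusted p under 0.05. With no filter 19608 of 41374 genes did. In total 7066 genes were called at least 2-fold higher in at least 1 cluster against the mean of the others. Within that set 5489 genes were higher in 1 cluster only, 1518 in 2 clusters and 59 in 3 or more. The spread between libraries was small, with a common coefficient of variation of 3.2% beyond counting noise. Across all settings tried, the number of genes that differed lay between 15360 and 22363, the highest without thinning, where clustering and testing used the same counts, all UMIs were tested, 24197 genes passed the filter and there were 8 clusters.

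Cluster 5 had the most distinct profile of the 7. With TMM it held 3296 higher genes and 2015 lower genes. Of the higher genes 541 were at least 8-fold and 94 at least 32-fold above the log-scale mean of the other clusters. No other cluster had more than 1 gene above 32-fold. Its 1398 genes that were at least 2-fold higher than in each of the other 6 clusters, taken pairwise, compare with 237 in cluster 2 and 179 in cluster 3; with library size alone these numbers were 595, 212 and 226. The transcript CSS0024196 stood at 203 ± 29.2 CPM in cluster 5 (n = 3) and at 1.5 ± 0.587 CPM over the other clusters, a log2 fold change of 8.02 with TMM (SE 0.11, edgeR adjusted p = 1.97e-69) and 7.23 with library size alone. The transcript CSS0002730 stood at 1630 ± 225 CPM against 16.1 ± 1.06 CPM, a log2 fold change of 7.56 with TMM (SE 0.05, edgeR adjusted p = 2.03e-95) and 6.77 with library size alone, and both were higher in 3 of 3 libraries. Between 78.8% and 90.4% of the higher genes were called again in the matching cluster of the 10 other clusterings. The lowest share was at resolution 0.25, where cluster 5 shared its match with cluster 1. The balance of higher and lower genes depended on the scaling: 62.1% of calls in cluster 5 were higher with TMM and 14.4% (1574 higher, 9334 lower) with library size alone, which moved the median log2 fold change of all genes from -0.10 to -0.88. With library size alone cluster 3 (2376) and cluster 2 (1817) had more higher genes, while cluster 5 kept the most at 8-fold (281) and 32-fold (56) or more.

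Cluster 1 shared much of its higher expression with cluster 5. Of its 1070 higher genes, 845 (79%) were also higher in cluster 5, against 165 for independent lists, and 184 were higher in cluster 1 alone. When the references were made disjoint (clusters 2 and 6 for cluster 1, clusters 3, 4 and 7 for cluster 5), 1487 of 2008 genes were shared, against 330 for independent lists. Clusters 2 and 3 resembled each other (r = 0.94) and stood in opposite references, so genes low in both could enter both lists. Set against each other with TMM, cluster 5 exceeded cluster 1 at 2023 genes and cluster 1 exceeded cluster 5 at 705 genes. Library size alone lowered the median log2 fold change more in cluster 5 (-0.101 to -0.884) than in cluster 1 (-0.011 to -0.105). The 2 counts were not repeated with that scaling, so their balance may depend on it. Only 19 genes were at least 2-fold higher in cluster 1 than in every other cluster. The count of higher genes in the match of cluster 1 ranged from 518 to 3349 under the other clusterings. The 518 belonged to a match shared with cluster 4 and the 3349 to a match shared with cluster 5. The matches kept as few as 27.9% of the higher genes called here, after removal of the 10% of nuclei with the highest doublet scores. In that setting clusters 1 and 4 shared 1 match. With library size alone 44% of the calls in cluster 1 were higher, against 56.7% with TMM.

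Clusters 2 and 3 also shared higher genes. Cluster 2 held 1417 higher and 1568 lower genes, and cluster 3 held 1582 higher and 1114 lower genes. They shared 262 higher genes, against 105 for independent lists. With disjoint references (clusters 1 and 6 for cluster 2, clusters 4, 5 and 7 for cluster 3) their lists held 1698 and 2009 genes. They shared 494 genes, against 160 for independent lists. Clusters 1 and 5 resembled each other (r = 0.93) and stood in opposite references, so genes low in both could enter both lists. The mean profiles of clusters 2 and 3 correlated at r = 0.94 across genes, and both were farthest from cluster 5, at r = 0.80. Cluster 2 had 1015 and cluster 3 had 1108 genes higher in that cluster alone, and they differed from each other at 2645 genes, with 1104 higher in cluster 2 and 1541 higher in cluster 3. Under other clusterings the match of cluster 2 held 985 to 2046 higher genes and that of cluster 3 held 998 to 2383, keeping as few as 50% and 29.3% of those called here. The 2046 belonged to a match that clusters 2 and 3 shared. With library size alone the higher share of calls rose from 47.5% to 59.1% in cluster 2 and from 58.7% to 76% in cluster 3.

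**Figure D3:**
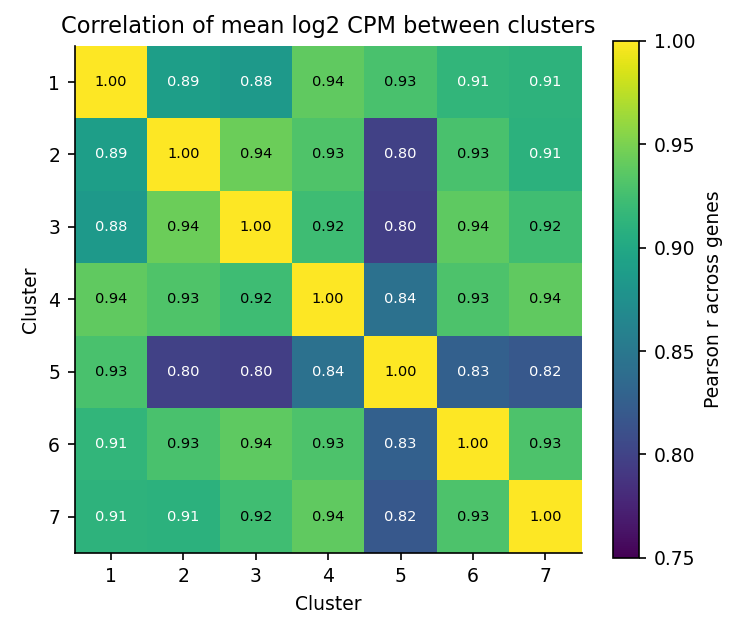
Pearson correlation across genes of mean log2 CPM between the 7 clusters (rows and columns), with the value in each cell and as colour from 0.75 to 1. Cluster 5 has its lowest values with clusters 2 and 3 (0.80) and its highest with cluster 1 (0.93).

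Cluster 4 held 601 higher and 1017 lower genes, and clusters 6 and 7 the fewest. The mean profile of cluster 4 correlated at r = 0.94 with those of clusters 1 and 7, and cluster 4 differed from cluster 1 at 2645 genes and from cluster 7 at 1252. Cluster 4 had 57 genes at least 2-fold higher than in each other cluster. Its match under other clusterings held 518 to 1769 higher genes and kept as few as 17.1% of those called here. Both lowest values came from a match shared with cluster 1, after removal of the 10% of nuclei with the highest doublet scores. Cluster 7 held 436 higher and 287 lower genes, of which 46 were at least 8-fold higher, and 130 genes were at least 2-fold higher than in each of clusters 1 to 5. Cluster 6 held 301 higher and 215 lower genes, and 14 genes were at least 2-fold higher than in each of clusters 1 to 5. Clusters 6 and 7 differed from each other at 402 genes, the fewest of any pair, but they also held the fewest UMIs per sum. Their counts moved with the clustering, from 182 to 883 higher genes in the match of cluster 6 and from 60 to 678 in that of cluster 7. The 678 belonged to a match shared with clusters 4 and 6. The matches of clusters 6 and 7 kept as few as 0.332% and 1.38% of the genes called here. Both values were at the minimum of 1000 UMIs, which lies above the median depth of either cluster. Without thinning 2.99% and 1.83% were kept. In both settings clusters 6 and 7 shared 1 match. With library size alone 88.7% of calls in cluster 6 and 91.5% in cluster 7 were higher, against 58.3% and 60.3% with TMM.

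**Figure D4:**
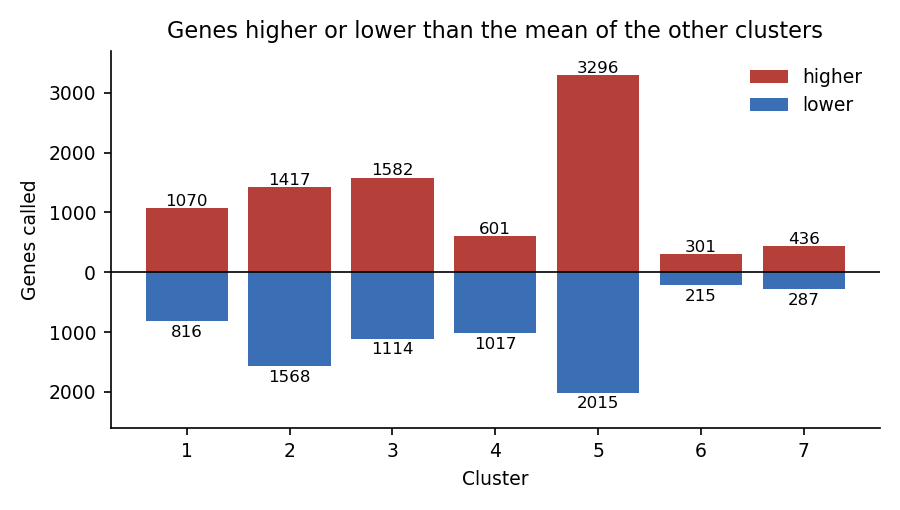
Number of genes (y axis) called at least 2-fold higher (red, upward) or lower (blue, downward) in each cluster (x axis) than the mean of the other clusters, by edgeR at an adjusted p under 0.05 with TMM scaling. Cluster 5 has the most of both (3296 and 2015) and cluster 6 the fewest (301 and 215).

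The 2 lowest fold changes belonged to genes without a UMI in a shallow cluster. The gene CSS0000335 had 0 UMIs in the held-out counts of cluster 7 and 6.13 ± 0.468 CPM over the other clusters, with its highest level, 22.3 CPM, in cluster 5. With 3 counts as the floor it was at least 4.25-fold lower in cluster 7 (edgeR adjusted p = 0.00246, lower in 3 of 3 libraries). The gene CSS0027311 had 0 UMIs in the held-out counts of cluster 6 and 5.04 ± 0.304 CPM over the others, at least 3.52-fold lower (edgeR adjusted p = 0.00754, lower in 3 of 3 libraries). It reached 17.9 CPM in cluster 5. For both genes cluster 5 raised the mean of the others, so these limits say little about the remaining clusters. Both calls ended under some other clusterings, and that of CSS0027311 also without replicate 3, where its log2 fold change was -6.25 against -6.21 with all libraries and its adjusted p 0.0552.

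The most abundant transcript, CSS0027849, was named after its values were seen. It made up 3.8% ± 0.118 of the UMIs of cluster 1, 2.66% ± 0.124 of cluster 2, 2.69% ± 0.0698 of cluster 3, 2.63% ± 0.16 of cluster 5 and 3.8% ± 0.36 of cluster 7 (n = 3). Relative to the mean of the other clusters its log2 fold change was 0.41 (SE 0.03) in cluster 1, -0.40 (SE 0.03) in cluster 2 and -0.45 (SE 0.03) in cluster 3, none of which reached 2-fold. In cluster 5 it was 0.49 with TMM and -0.31 with library size alone, a move as large as that of the median gene (-0.10 to -0.88). With library size alone it was -0.25 in cluster 3, and 0.23 and 0.32 in clusters 6 and 7, against 0.01 and 0.03 with TMM.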

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

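Alternatives chosen only after seeing the data were library-size scaling alone, the second best restart, 10 components, removal of the top 10% of doublet scores, and leaving out each replicate for the shares, nuclei, UMIs and library correlation. The number of genes that differ among clusters stayed within 1.5 times of 17720 under each alternative that gave this count; the contrast against the sum of the rest gives none. RLE scaling and the fit with no replicate block moved none of the 14 cluster counts by 1.5 times, and neither did leaving out any replicate. The genes themselves changed more: without 1 replicate, 55.5% to 63.1% of the higher genes of cluster 6 and 65.1% to 76.4% of those of cluster 7 were called again, against 91.9% to 94.3% in cluster 5. Without the replicate block 17616 genes differed.

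Without 1 replicate, 15360 to 16543 genes differed; nuclei per library ranged from 15794 to 16934.5, median UMIs from 1645 to 1877, and the mean library correlation from 0.9983 to 0.9984. That correlation was 0.9948 with log2(CPM + 0.1) and 0.9975 for genes with a mean CPM of at least 1. With at least 500 genes and 1000 UMIs, 12749.7 nuclei per library remained, at a median of 2274.5 UMIs.

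Scaling and test moved some counts. With library size alone, higher genes numbered 2376 in cluster 3, 1574 in cluster 5, 693 in cluster 6 and 958 in cluster 7, and lower genes 9334 in cluster 5, 88 in cluster 6 and 89 in cluster 7. This scaling shifted the median log2 fold change of all genes to -0.88 in cluster 5 and to between -0.11 and 0.27 in the other clusters. DESeq2 gave 190 lower genes in cluster 7. With no filter, higher genes numbered 2257, 2561 and 910 in clusters 2, 3 and 4. Against the sum of the rest, lower genes numbered 2029, 1810, 1852, 453 and 581 in clusters 1, 3, 4, 6 and 7, and higher genes 171 in cluster 6; this reference weights clusters by their UMIs.

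The clustering moved more, and a cluster is followed here through its best match. At resolution 0.25 (3 clusters), higher genes were 3349 in cluster 1 and 678 in clusters 6 and 7, lower genes 2792, 2457, 2457, 1106 and 1106 in clusters 1, 2, 3, 6 and 7, and shares 22.4%, 29.3%, 29.3%, 48.2%, 22.4%, 48.2% and 48.2% in clusters 1 to 7, since several clusters shared a match. At resolution 1.0, higher genes were 1705, 182 and 60 in clusters 1, 6 and 7, lower genes 1253, 867, 56 and 14 in clusters 1, 2, 6 and 7, and shares 14.7%, 12.9%, 9.28%, 10.3%, 9.58% and 7.4% in clusters 1 to 6. With centring by library, higher genes were 659 and 78 and lower genes 523 and 81 in clusters 6 and 7, and shares 22.4%, 18.9%, 12.1%, 14.6%, 12.3% and 12.1% in clusters 1 to 6. Another thinning seed gave 1049 and 883 higher genes in clusters 4 and 6, 837 and 451 lower genes in clusters 6 and 7, and shares of 25%, 20.9%, 15.9%, 7.79%, 5.94%, 15.2% and 9.37%. Without thinning, higher genes were 1972 and 1769 in clusters 1 and 4, lower genes 1704, 1805 and 375 in clusters 1, 4 and 6, and shares 12.6%, 17.2%, 7.87%, 8.6%, 12.7%, 29.4% and 29.4%. Keeping the 4 called doublets gave 661 and 155 higher and 461 and 146 lower genes in clusters 6 and 7, and shares of 19.5%, 20.6%, 13.7%, 15%, 12.7%, 12.2% and 6.37%; so small a change of input moved the partition, as restarts did. With at least 500 genes and 1000 UMIs, higher genes were 1682, 2383, 1460 and 502 in clusters 1, 3, 4 and 6, lower genes 1234, 1567, 833 and 833 in clusters 1, 4, 6 and 7, and shares 17.5%, 21.0%, 14.9%, 9.35%, 10.5%, 22.4% and 22.4%. The second best restart gave 612, 1029, 696 and 93 higher genes in clusters 1, 4, 6 and 7, lower genes 1530, 442 and 73 in clusters 4, 6 and 7, and shares of 20.3%, 22.3%, 15.9%, 7.47%, 14.1% and 12.9% in clusters 1 to 6. With 10 components, higher genes were 998, 1136 and 154 in clusters 3, 4 and 7, lower genes 131 in cluster 7, and shares 14.3%, 13.5%, 13.8%, 5.59%, 12.2%, 19.2% and 13.5%. Without the top 10% of doublet scores, cluster 1 had 518 higher and cluster 5 had 3197 lower genes, and shares were 28.6%, 20.02%, 15.2%, 28.6%, 14.2%, 8.86% and 6.36%. Several of these alternatives changed the partition itself by construction; beyond that, the cause was not tested.

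The estimated correlation for gene lists was not run, because no list could be matched to the identifiers. CSS0024196 and CSS0002730 stayed called in cluster 5 under all alternatives, while CSS0000335 and CSS0027311 together lost 8 calls, with log2 fold changes reaching -1.05 and -0.90. Depth limits small folds in shallow clusters: in simulated cluster 7 the fit recovered 83.5% of the genes raised 2.5-fold, against 93% in simulated cluster 5.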

Other observations

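The tests of cluster 5 on doublet scores, on doublets of other clusters and on its library size without abundant genes, and that of the share mixed into cluster 1, were chosen only after the result was seen; that of the spread of ratios in cluster 1 was set after the overlap with cluster 5 was seen but before its own result. Beyond the pairs described above, shared higher genes exceeded the number for independent lists for clusters 3 and 6 (96 against 22.3), 6 and 7 (16 against 6.14), 4 and 7 (30 against 12.3), 2 and 6 (42 against 19.95), 2 and 4 (78 against 39.8), 3 and 7 (63 against 32.3), and, by little, 1 and 4 (32 against 30.1). These overlaps were not repeated with disjoint references.

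Genes listed next to each other tended to share their pattern over clusters. The mean correlation of the 7 cluster means between tested genes in adjacent rows of the gene list was 0.178 over 11137 pairs, above the highest of 1000 shuffles of the rows (0.023). It fell to 0.0914 at 2 rows apart, 0.0507 at 5 rows and 0.0346 at 10 rows, and stood at 0.0078 at 50 rows, within the range of the shuffles. A candidate explanation is that the list follows the order of genes on the chromosomes, so that neighbours include tandem copies or share regulation. The correlation of 0.178 fits an informative order but cannot tell neighbours with shared regulation from near-identical copies that share reads, since no sequences or positions of these genes were used here.

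Cluster 5 stood apart in its number of large folds and in its few genes per nucleus at equal depth, with both scalings for the folds. With TMM and without its 50 most abundant genes 99.6% of its other higher genes were called again. TMM trims such genes beforehand, so this decides nothing. With library size alone their removal moved its median log2 fold change from -0.884 to -0.652. The 50 genes took 23.3% of its UMIs, too few for their removal to undo the whole shift. They are thus not the whole cause of that shift, and the part of other higher genes was not examined. With library size alone 595 genes were at least 2-fold higher in cluster 5 than in each other cluster. This argues against doublets drawn evenly from the other clusters, since such a mixture cannot exceed its highest part. The doublet score (median difference -0.029) decides nothing, because a cluster that lies apart can score low for that reason alone. The scaling stays open as a cause of its rank in higher genes (1574 with library size alone, under the 2376 of cluster 3) and of its count of lower genes (9334). No biological explanation was tested, since the design names no cell type and the genes carry no names.

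Cluster 1 shared 845 of its 1070 higher genes with cluster 5. RNA of whole cluster 5 nuclei mixed into cluster 1, as doublets, would carry all cluster 5 genes in 1 ratio. Leaked RNA need not keep the proportions seen in nuclei, so the limit below does not cover it. The limit came from 151 genes at least 8-fold higher in cluster 5 than in each of clusters 2, 3 and 4. Their level in cluster 1 was 0.0312 of that in cluster 5 at the 10th percentile and 0.164 at the median, which limits such a share. The 845 genes would need a median share of 0.79. Of them 99.6% would need more than 0.0312 (97.4% to 98.2% in single libraries, each against its own 10th percentile). The needed shares follow largely from the 2-fold call that picked these genes, so the 99.6% is no separate test. What the values show is narrower: the 10th percentile limits an even admixture of nuclei to a share of 0.0312. That such a share is too small for most of the 845 calls follows from the 2-fold threshold. The spread of the excess over those 151 genes (upper over lower quartile 10.01 in cluster 1, 4.13 and 4.5 in clusters 6 and 7, at most 1.12 in simulations with counting noise alone) decides nothing, since genes differ in their own expression. The median doublet score of cluster 1 lay above that of the other nuclei in each library, by 0.00577, 0.00834 and 0.00577. In clusters 2, 6 and 7 it did so too. Without the 10% of nuclei with the highest scores, the match of cluster 1 kept 27.9% of its higher genes. Cluster 4 shared that match, so a merge of clusters and a loss of doublets cannot be told apart there. An admixture from part of cluster 5 and leaked RNA of other proportions stay open, and no biological explanation was tested.

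Clusters 6 and 7 held shallow nuclei. If they were shallow samples or mixtures drawn evenly from clusters 1 to 5, no gene could stand above all of these clusters beyond noise. In cluster 7, 130 genes were at least 2-fold higher than in each of clusters 1 to 5 with TMM. With library size alone 124 genes were at least 2-fold higher than in each other cluster. This argues against an even sample or mixture as the whole cause, although the match of cluster 7 under other clusterings kept a median of 10.2% of its higher genes. Clustering picks nuclei by expression, so a shallow subset of 1 cluster could exceed the mean of that cluster, and such a subset stays open. In cluster 6 there were 14 genes above each of clusters 1 to 5, between the limits set beforehand (at most 5 and more than 50). A shallow mixture and a population of its own cannot be told apart there. The shares of both clusters were lowest in replicate 2, the deepest library: 7.42% against 8.06% and 7.83% in cluster 6. In cluster 7 the share was 6.39% there, against 7.93% and 7.25%. Cluster 3, whose nuclei were deep, was also lowest there (17.2%), so 3 libraries do not settle whether depth sets these shares. Leaked RNA and biological explanations were not tested.

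Chance arrangements of the sums were examined by permuting the cluster labels within each library, over 100 splits including the real one. For the number of genes that differ among clusters (17720), 1 split, the real one, gave as many, and the highest other gave 7963. For higher genes, the real split alone (1 of 100) gave as many in clusters 2 (1417, highest other 862), 3 (1582, highest other 835) and 5 (3296, highest other 853). The same held for lower genes in clusters 2 (1568, highest other 788), 3 (1114, highest other 39), 4 (1017, highest other 505) and 5 (2015, highest other 707). In cluster 1, 3 splits gave as many higher genes (1070, highest other 2863) and 2 gave as many lower genes (816, highest other 1318). In cluster 4, 4 splits gave as many higher genes (601, highest other 2158). In cluster 7, 4 splits gave as many higher genes (436, highest other 3094) and 3 gave as many lower genes (287, highest other 1618). In cluster 6, 8 splits gave as many higher genes (301, highest other 1095), above the limit of 5 of 100 set beforehand. There 2 gave as many lower genes (215, highest other 649). For the other counts under 5 of 100 splits reached the real value, but the labels were made from expression over all libraries together, so that real sums of a cluster resemble each other by construction. The splits therefore exclude no chance partition in any cluster, cluster 6 included, and no adjustment was made over the 15 counts. Splits with several times the real count may reflect the structure of the sums, since a permuted group can hold sums of 1 cluster from more than 1 library. The groups of these splits were not examined.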
